A study of Homo sapiens with 12 samples.

How the data were processed

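RNA of Cal33 cells was measured on 12 one-colour Agilent whole-genome arrays, 1 sample per array. Per the labels, the arrays form 4 groups of 3: a clone that keeps 1 of 3 SLC3A2 alleles and a clone with all 3 alleles, each without irradiation or after 4 Gy of X-rays. The groups were taken from the sample titles. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Each genotype is represented by 1 clone.

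The authors deposited the scanner output of each array, with intensity values per spot on a linear scale, and a value table of the whole series. Per the file headers, the spots were quantified with Agilent Feature Extraction 10.7.3.1, and the submitters' processing notes name Agilent Feature Extraction 10.7.1.1. Per the file headers, the processed signal is a background-corrected intensity of the green channel. The scale of the authors' value table is not given in the sources used here. Its 12 columns hold the same sorted values, with a median of 26 and a maximum of 369338 in each, and rank the spots like the processed signal (lowest rank correlation 0.9974), so it was read as linear intensity after quantile normalization, and no centring of genes was found. Its direction needs no choice, because each column is 1 sample.

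Of 62976 spots on each array, 2075 controls were left out. Spots with an outlier flag were set to missing, replicate spots of a probe were averaged, and 58201 probes remained. The log2 of the processed signal minus the 75th percentile of the array was the value used. A probe was tested where it was well above background on all 3 arrays of at least 1 group and had at least 2 values per group. Probes were named through their RefSeq accession with a gene table of assembly GRCh38.p14, used for names and for the order of neighbouring genes. A symbol was found for 24751 of 25277 probes with an NM accession and for 31104 probes in all, and the other 27097 kept the name in the files. For each gene the probe with the highest mean over the 12 arrays was used, which gave 24291 genes, 15696 of them with a symbol. The number of arrays limits the precision of all values.

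Linear models were fitted to the 4 groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), with 8 residual degrees of freedom. The 5 comparisons were the dose effect in each clone, the difference between the clones at each dose, and the difference of the dose effects. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Gene lists fixed before the data were examined, 27 in number, were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. A list needed at least 5 tested members, SLC3A2 was left out of all, and the endothelial list had 4 and was not tested. Camera with an estimated correlation and fry were run beside it. A gene well above background on no array of the dimmer group is given as at least N-fold: the mean of the brighter group against the mean of, per array, the higher of the lowest signal well above background and the gene's own signal. This bound holds for the main processing only, and under other settings some of these genes differed by less.

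Genes are named by a rule set before the data were examined. For each comparison these are the 10 largest rises and 10 largest falls (5 and 5 for the difference of the dose effects) past the threshold that carry an official symbol, do not overlap between the groups compared (not required for the difference of the dose effects), are not Y-linked or XIST, and are well above background on all 3 arrays of the higher group. Up to 4 members of each list past its threshold, 9 fixed genes of amino acid transport and the p53 pathway, and genes next to SLC3A2 that passed were added. Some genes that this rule names are not reported here.

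Slides were read from the files and numbered 1 to 3. Slide 1 held the 3 unirradiated knockout-labelled arrays and nothing else, slide 3 held 1 irradiated wild type-labelled array, and slide 2 held the other 8 arrays. The dose effect in the wild type-labelled clone and the clone difference after 4 Gy were therefore also fitted within slide 2, while slide and group cannot be told apart in comparisons that use the unirradiated knockout-labelled arrays. Alternatives covered quantile and median scaling, normexp correction (offset 50), no filter and a strict filter on dim probes, the mean of a gene's probes, only the groups compared, a variance trend, slide as a block, a replicate block, the authors' value table, a 2-fold threshold and each array left out in turn. For SLC3A2 and the gene counts, each array was also shifted to the mean of the 7 E1A spike-ins whose spots were all well above background and unsaturated. The normexp alternative was planned on mean spot signals; that column was not used here, and median spot and background signals were taken in its place.

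The fit was tested on simulated data with 24269 genes, 50 of them changed by each of the folds 1.5, 2, 4 and 8. Of genes changed 2-fold and 4-fold, 66% and 78% were recovered for the dose effect in the wild type-labelled clone, and 58% and 92% in the knockout-labelled clone. For the clone difference these shares were 54% and 90% without irradiation and 78% and 88% after 4 Gy. For the difference of responses they were 46% and 74%. Noise was drawn independently for each gene. More genes were changed than the 2 that passed in the wild type-labelled clone, which loosens the adjusted threshold, so recovery there may be lower than simulated.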

Results

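Gene expression was measured in Cal33, an established squamous carcinoma line of the tongue, in clones that differ in the number of intact SLC3A2 alleles. SLC3A2 encodes the heavy chain of CD98, which carries several amino acid transporters to the cell surface and binds integrins. The design asked how the clones differ and how each responds to a dose of 4 Gy. It comprised 4 groups of 3 arrays. The 75th percentile of the processed signal lay between 342.9 and 722.1 per array, and 47.93% to 64.48% of probes were well above background. The unirradiated knockout-labelled arrays had the lowest 75th percentiles (342.9, 355.3 and 360.9). Replicate 2 of that group stood apart, with 64.48% of probes well above background and a mean net signal of negative controls of 38.2, against 18.7 to 22 on the other 11 arrays. Irradiated wild type-labelled replicate 3, the only array of this series on its slide, had the highest 75th percentile, 722.1, and 62.74% of probes well above background.

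The targeted gene was examined first. SLC3A2 was well above background on each of the 12 arrays. As log2 over the 75th percentile, replicates 1, 2 and 3 had 6.09, 5.70 and 5.73 in the unirradiated wild type-labelled clone and 5.61, 5.50 and 5.65 in the unirradiated knockout-labelled clone. After 4 Gy they had 6.01, 5.57 and 5.48 and, in the knockout-labelled clone, 5.45, 5.67 and 5.55. The mean was 5.84 ± 0.22 (SD, n = 3) in the unirradiated wild type-labelled clone and 5.59 ± 0.08 (SD, n = 3) in the unirradiated knockout-labelled clone. After 4 Gy the means were 5.68 ± 0.29 (SD, n = 3) and 5.56 ± 0.11 (SD, n = 3). The difference was -0.25 (SE 0.15, adjusted p = 0.219, limma) without irradiation and -0.13 (SE 0.15, adjusted p = 0.6, limma) after 4 Gy. The 95% confidence intervals ran from -0.60 to 0.09 and from -0.47 to 0.22, which on this scale leave out the -1.58 that a level in proportion to 1 of 3 copies would give. That value assumes that the edited alleles give no RNA that the probe detects. Relative to the mean of 7 spike-ins of known sequence added to each sample, the difference was -1.25 (95% confidence interval -1.62 to -0.89) without irradiation, which includes -1.58, and -0.77 (-1.13 to -0.40) after 4 Gy, which does not. Against single spike-ins it ran from -1.71 to -0.52 and from -0.83 to -0.69. The median of all genes shifted alike, to -1.07 and -0.71, so the spike-in scale does not set SLC3A2 apart from other genes. Relative to the 75th percentile the values of the clones did not overlap without irradiation and overlapped after 4 Gy, with neither difference past the threshold, and the clones are called knockout-labelled and wild type-labelled below. A single probe measured SLC3A2, and its place relative to the edited part of the gene is not given in the sources used here.

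All further values are relative to the 75th percentile of each array, and small differences can change direction on the spike-in scale. Relative to the spike-ins, the median of all genes was -1.07 between the clones without irradiation and -0.71 after 4 Gy (-0.07 at both doses relative to the 75th percentile). For 4 Gy it was 0.25 in the wild type-labelled and 0.55 in the knockout-labelled clone (0 and -0.06 relative to the 75th percentile). On the spike-in scale 19985 genes differed between the clones without irradiation, 19200 of them lower in the knockout-labelled clone, and 16090 after 4 Gy, 15166 of them lower, while 13427 genes rose and 31 fell with 4 Gy in the knockout-labelled clone.

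**Figure D1:**
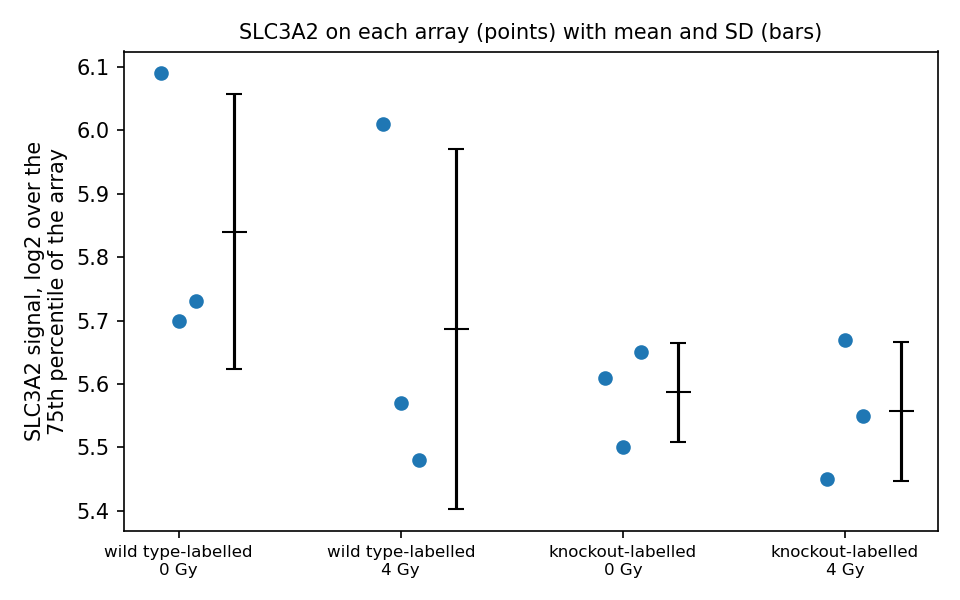
SLC3A2 signal on each array, as log2 over the 75th percentile of that array (vertical axis), in the 4 groups (horizontal axis); points are arrays, and bars give the mean and SD of 3 arrays. The values lie between 5.45 and 6.09, and the groups of both clones overlap after 4 Gy.

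After 4 Gy, genes of keratinocyte differentiation were higher in the knockout-labelled than in the wild type-labelled clone. Of 35 measured, 30 were higher, none was lower and 5 did not pass (30 higher and none lower when adjusted over the list alone), with a median log2 difference of 3.54 (camera adjusted p = 1.95e-24; adjusted p = 0.0815 with an estimated correlation). KRT1, the keratin of suprabasal epidermis, was at least 288-fold higher in the main processing, with log2 differences from 6.1 to 10.05 across settings. KRT6B, a keratin of activated epithelium, was 538-fold higher (log2 9.07, SE 0.61, adjusted p = 6.48e-06). KRTDAP and SBSN, secreted proteins of differentiating keratinocytes, were also higher; each was well above background on 1 of 3 wild type-labelled arrays, and across settings their log2 differences ran from 6.43 to 8.92 and from 5.27 to 7.54. Outside the list, LAMA1, a laminin chain, was at least 138-fold higher, ADH7, an alcohol dehydrogenase that oxidises retinol, at least 75-fold, and the kallikrein KLK12 at least 68.4-fold. The zinc finger genes ZNF573 and ZNF350 were at least 64.2-fold and 50-fold higher, and GPR15LG, a ligand of the receptor GPR15, at least 48.1-fold. These bounds for genes outside the list hold for the main processing. Each of these genes differed by less under at least 1 other setting, with lowest log2 differences of 4.84 for LAMA1 and 3.71 for GPR15LG.

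Among interferon-stimulated genes, of 33 measured after 4 Gy, 26 were higher, 2 lower and 5 did not pass (27 higher and 2 lower when adjusted over the list alone), with a median of 1.45 (camera adjusted p = 1.35e-13; adjusted p = 0.378 with an estimated correlation). RSAD2, the antiviral protein viperin, was 34-fold higher (log2 5.09, SE 0.36, and 3.92 to 5.41 across settings), OASL 17.3-fold and IFIT3 11.8-fold. XAF1 was at least 2.91-fold higher in the main processing, with log2 differences from 0.84 to 4.14 across settings. Of 20 basal squamous genes, 7 were higher and 1 lower (8 and 2 when adjusted over the list alone; camera adjusted p = 0.00853, and 0.425 with an estimated correlation), among them the basal keratins KRT17 at 6.6-fold and KRT14 at 6.47-fold, and TP63, the transcription factor of squamous epithelium, at 2.2-fold. In the list of ATF4 targets and the amino acid response, 12 of 33 genes were higher and 1 lower (14 and 2 when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.000448; adjusted p = 0.392 with an estimated correlation). NUPR1, a stress-induced regulator, was 13.1-fold higher, ATF3 3.24-fold (log2 0.9 to 1.92 across settings), and PYCR1, of proline synthesis, 2.7-fold. The asparagine synthetase ASNS was 2.34-fold higher (log2 1.23, SE 0.27, adjusted p = 0.00775) and the glutamine transporter SLC1A5 1.33-fold (adjusted p = 0.00799). SLC7A5 and SLC7A11, which encode light chains that pair with CD98, differed by 0.23 (SE 0.17, adjusted p = 0.375) and 0.06 (SE 0.22, adjusted p = 0.889). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was 5.37-fold higher (log2 2.42, SE 0.23, adjusted p = 6.02e-05, and 1.55 to 2.61 across settings). The list of p53 targets had a median of 0.10 and did not pass (camera adjusted p = 0.323, but 0.0204 by fry). MDM2 differed by 0.39 (SE 0.10, adjusted p = 0.0128) and MYC by 0.02 (SE 0.19, adjusted p = 0.963). Amino acid transporters (median 0.23, camera adjusted p = 0.0518) and integrins (median 0.11, camera adjusted p = 0.333) did not pass as lists. The call of amino acid transporters depended on the processing: they passed with quantile normalization (0.0233), median scaling (0.0499), no filter (0.00688), the mean of probes (0.0266), the replicate block (0.0464) and the authors' table (0.0199), without MAKO_4Gy replicate 3 (0.0402) or WT_4Gy replicate 1 (0.0344), and by fry (3.85e-05).

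Lower in the knockout-labelled clone after 4 Gy were genes of mitosis, of non-homologous end joining and genes next to SLC3A2. Of 32 mitotic genes, 16 were lower and none higher (17 lower and 1 higher when adjusted over the list alone), with a median of -0.40 (camera adjusted p = 5.93e-05; adjusted p = 0.509 with an estimated correlation). Among them the centromere histone CENPA differed by -0.82 (SE 0.13) and the checkpoint kinase BUB1 by -0.76 (SE 0.14). Of 14 end-joining genes, 5 were lower and none higher (5 and none when adjusted over the list alone; camera adjusted p = 0.0177, and 0.378 with an estimated correlation). PRKDC, the catalytic subunit of DNA-dependent protein kinase, differed by -1.03 (SE 0.22, adjusted p = 0.00693), PAXX by -0.81 (SE 0.12) and XRCC5, which encodes Ku80, by -0.60 (SE 0.08). Of 25 measured neighbours of SLC3A2, 12 were lower and 2 higher (15 and 2 when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.00853; adjusted p = 0.378 with an estimated correlation). RTN3 differed by -1.14 (SE 0.19), although its other tested probe had the opposite sign, and GANAB by -0.65 (SE 0.12), whereas PLAAT4 was higher by 2.63 (SE 0.18). Histone genes were shifted up (5 of 19 higher, 2 lower, the same counts when adjusted over the list alone, median 0.30, camera adjusted p = 0.0177, 0.573 with an estimated correlation and 0.0869 by fry), with H1-1 at 2.51-fold. The largest single fall was PLS3, an actin-bundling plastin, at least 1170-fold lower in the main processing, with log2 differences from -12.1 to -7.77 across settings. In the main processing NPTX1, KLF12, UCHL1 and HTR3D were at least 39.9-fold, 30.4-fold, 29.5-fold and 28.3-fold lower, and CPPED1, DSEL, COCH and NR3C2 at least 22.1-fold, 17.6-fold, 10.1-fold and 7.67-fold. Each of these differed by less under at least 1 other setting, with smallest log2 differences of -2.96 for NPTX1 and -1.38 for NR3C2. CLMP, well above background on 2 of 3 knockout-labelled arrays, differed by -6.46 to -4.07 on the log2 scale across settings.

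In all, 6521 of 24291 genes differed after 4 Gy, 3004 higher and 3517 lower in the knockout-labelled clone, and 1826 of them by at least 2-fold (1147 higher, 679 lower). On the arrays of slide 2 alone 5517 genes differed, 4812 of them shared with the 6521, and with slide 3 as a block 5121 did. Within slide 2 the list medians were 3.69 for keratinocyte differentiation, 1.46 for interferon, 0.41 for basal squamous genes, 0.18 for ATF4, 0.35 for histones, -0.38 for mitosis, -0.24 for end joining and -0.46 for neighbours of SLC3A2, and each kept an adjusted p under the threshold. None of the list calls of any comparison held with an estimated correlation. The histone call was lost without MAKO_4Gy replicate 2 (adjusted p = 0.0508) or WT_4Gy replicate 2 (0.0885), the basal squamous call without MAKO_4Gy replicate 2 (0.0642), and the end-joining call with the mean of probes (0.0674).

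**Figure D2:**
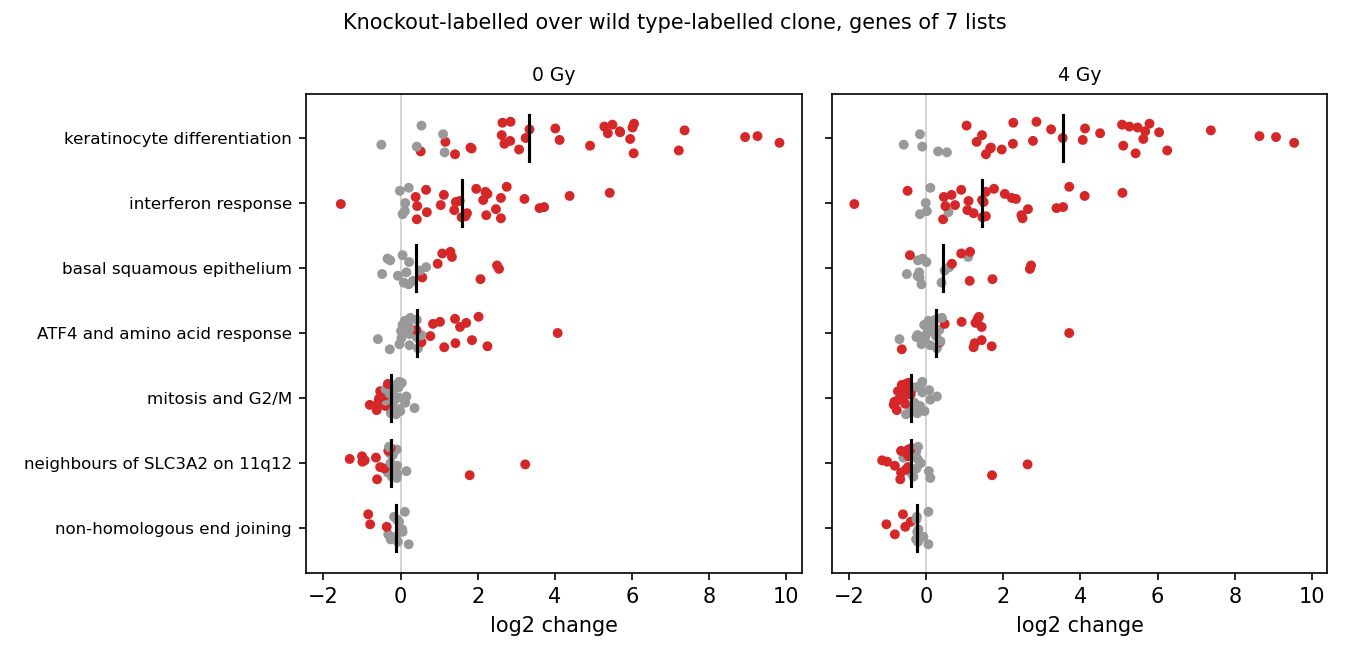
Log2 difference of the knockout-labelled over the wild type-labelled clone (horizontal axis) for the measured genes of 7 lists (vertical axis), on values over the 75th percentile of each array, without irradiation (left) and after 4 Gy (right); each point is a gene, red where its adjusted p is under 0.05, and vertical bars are list medians. Keratinocyte differentiation has the highest median at either dose, 3.34 and 3.54.

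Without irradiation, 5 of the 8 lists called after 4 Gy passed as well, and 4 others did. Histones (median -0.09, camera adjusted p = 0.711, 0.495 by fry), end joining (camera adjusted p = 0.381, 0.00902 by fry) and neighbours of SLC3A2 (camera adjusted p = 0.0934, 0.00488 by fry) did not pass by camera, although the neighbours did without a filter (0.0175), with normexp (0.0138) and with the replicate block (0.047). Keratinocyte differentiation was higher in the knockout-labelled clone (30 of 35 higher, none lower, 32 higher when adjusted over the list alone, median 3.34, camera adjusted p = 5.84e-21, and 0.126 with an estimated correlation), with KRT1 at least 227-fold and KRTDAP at least 318-fold higher and KRT6B at 486-fold. Of 33 interferon genes, 27 were higher and 1 lower (27 and 1 when adjusted over the list alone; median 1.58, camera adjusted p = 7.39e-13, and 0.298 with an estimated correlation), with RSAD2 at 42.7-fold and OASL at 20.8-fold. Of 33 genes of the ATF4 list, 15 were higher and none lower (16 and none when adjusted over the list alone; camera adjusted p = 1.13e-05, and 0.298 with an estimated correlation), with NUPR1 at 16.8-fold and ASNS at 2.19-fold. Of 27 amino acid transporters, 11 were higher and 4 lower (11 and 5 when adjusted over the list alone; camera adjusted p = 0.0132, and 0.136 with an estimated correlation), with SLC6A14, which takes up neutral and basic amino acids, at least 9.86-fold and SLC7A8, a partner of CD98, 6.4-fold higher. Of 30 p53 targets, 10 were higher and 2 lower, the same counts when adjusted over the list alone (camera adjusted p = 0.0327, and 0.154 with an estimated correlation), with TP53INP1 at 6.02-fold and CDKN1A, well above background on 2 of 3 wild type-labelled arrays, higher by 1.97 to 3.25 on the log2 scale across settings. Basal squamous genes (8 of 20 higher, none lower, 8 and 1 when adjusted over the list alone, camera adjusted p = 0.00155, and 0.3 with an estimated correlation), genes of autophagy and the lysosome (10 of 26 higher, 2 lower, 12 and 2 when adjusted over the list alone, camera adjusted p = 0.0132, and 0.3 with an estimated correlation) and secreted factors of senescent cells (8 of 26 higher, none lower, 7 and none when adjusted over the list alone, camera adjusted p = 0.038, and 0.526 with an estimated correlation) were shifted up; the last included the cytokines IL1A at 6.06-fold and IL1B at 4.77-fold. Mitotic genes were shifted down (10 of 32 lower, none higher, 9 lower when adjusted over the list alone, median -0.24, camera adjusted p = 0.044, and 0.657 with an estimated correlation). In the main processing PLS3 was at least 576-fold and UCHL1 at least 16.7-fold lower. Across settings their log2 differences ran from -11.11 to -6.95 and from -6.63 to -2.39. KRT1, KRTDAP and SLC6A14, also given as at least N-fold, had lowest log2 differences of 6.08, 6.34 and 2.11 across settings.

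In all, 9797 genes differed without irradiation, 4132 higher and 5665 lower (42.2% higher). With normexp correction the split was 5728 higher and 4437 lower (56.4% higher). Among genes with a symbol 3291 were higher and 3222 lower in the main processing. The unirradiated knockout-labelled arrays are the only ones of this series on slide 1, so slide and group cannot be told apart here. Of the genes higher after 4 Gy, 78.5% were also higher without irradiation (2359 genes, against 511 for independent lists), and of those lower, 59.7% were also lower (2099 genes, against 820 for independent lists); no array is shared by these 2 comparisons. With normexp correction the calls of p53 targets (adjusted p = 0.532), amino acid transporters (0.0632), autophagy (0.147) and senescence factors (0.154) were lost. Single arrays decided 3 calls: p53 targets were lost without MAKO_0Gy replicate 1 (0.0567) or 3 (0.0543), senescence factors without MAKO_0Gy replicate 1 (0.0567), and mitosis without MAKO_0Gy replicate 1 (0.0567), 2 (0.0545) or 3 (0.1) or WT_0Gy replicate 2 (0.133) or 3 (0.0546).

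In the wild type-labelled clone, 4 Gy changed few single genes, and the calls of gene lists depended on the test. The time between irradiation and the collection of RNA is not given in the labels. GAS2L3, a cytoskeletal protein of dividing cells, fell by 1.04 on the log2 scale (SE 0.11, adjusted p = 0.0464, limma), and the other gene past the threshold was a transcript without a symbol here, ENST00000504382, named after its value was seen, which rose by 1.17 (SE 0.13). Of 32 mitotic genes, 28 had lower values and the median was -0.24 (camera adjusted p = 1.69e-12); none passed over all genes and 10 were lower when adjusted over the list alone. All 19 histone genes had lower values, with a median of -0.27 (camera adjusted p = 3.44e-08), and none passed by either adjustment. Interferon genes had a median of 0.16, with 28 of 33 values higher (camera adjusted p = 0.0194) and none past either adjustment. With an estimated correlation each adjusted p was 0.853, and fry, which tests a list against no change, called none of the 3 (adjusted p = 0.456 for mitosis, 0.464 for histones and 0.842 for interferon). Within slide 2 the medians were -0.25, -0.29 and 0.20. On the spike-in scale, on which lists were not tested, the median of all genes in this clone was 0.25. The list of p53 targets had a median of 0 (camera adjusted p = 0.772), and its members CDKN1A and MDM2 differed by 0.07 (SE 0.23) and 0.00 (SE 0.10).

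In total 2 of 24291 genes passed and 1601 had an unadjusted p under 0.05, where 1215 would be expected by chance. On the arrays of slide 2 none passed in limma and 1632 had an unadjusted p under 0.05, and leaving out any of the 6 arrays left no gene past it, with 866 to 1667 at an unadjusted p under 0.05. The interferon shift lost its call without WT_0Gy replicate 2 (adjusted p = 0.147), WT_0Gy replicate 3 (0.1) or WT_4Gy replicate 1 (0.59).

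**Figure D3:**
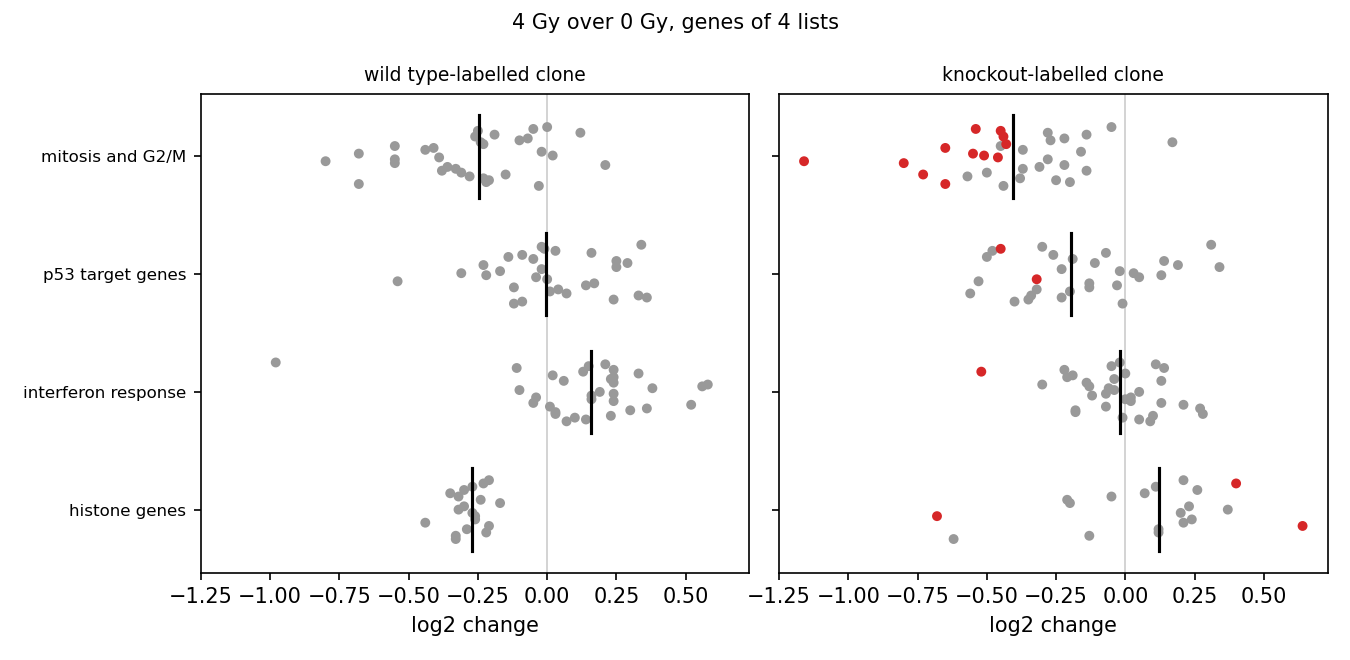
Log2 change of 4 Gy over 0 Gy (horizontal axis) for the measured genes of 4 lists (vertical axis), on values over the 75th percentile of each array, in the wild type-labelled clone (left) and the knockout-labelled clone (right); each point is a gene, red where its adjusted p is under 0.05, and vertical bars are list medians. The median of mitotic genes is -0.24 on the left and -0.40 on the right.

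In the knockout-labelled clone, genes of cell division fell after 4 Gy relative to the 75th percentile, with slide and dose not separable. On the spike-in scale, on which lists were not tested, the median of all genes moved from -0.06 to 0.55. That shift is larger than the median fall of the mitotic genes, so their fall holds only relative to the 75th percentile. Of 32 mitotic genes, 12 fell and none rose (19 fell when adjusted over the list alone), with a median of -0.40 (camera adjusted p = 1.72e-08; adjusted p = 0.807 with an estimated correlation). The kinetochore motor CENPE fell by 1.16 (SE 0.14, adjusted p = 0.000457), and CENPA, the cyclin CCNA2 and the mitotic kinesin KIF20A changed by -0.80 (SE 0.13), -0.73 (SE 0.15) and -0.65 (SE 0.13). GAS2L3 fell by 0.80 (SE 0.11, adjusted p = 0.000964). EGR1, an immediate early transcription factor, fell by 1.78 (SE 0.35, adjusted p = 0.00659). In the wild type-labelled clone EGR1 differed by -1.78 (SE 0.35) and did not pass (adjusted p = 0.303), and the difference of response was 0 (SE 0.49, adjusted p = 0.999). The matrix protein TINAGL1, UNCX and LAG3 changed by -1.28 (SE 0.11), -1.98 (SE 0.25) and -1.42 (SE 0.23). In the main processing NRROS was at least 2.35-fold lower, and across settings its log2 change ran from -2.79 to -0.9. Histone, interferon and p53 target lists did not pass in this clone (camera adjusted p = 0.525, 0.705 and 0.132), although histones passed with normexp (0.04) and p53 targets without MAKO_4Gy replicate 2 (0.0341) and by fry (0.00221). CDKN1A differed by -0.56 (SE 0.23, adjusted p = 0.145) and MYC by -0.53 (SE 0.19, adjusted p = 0.09). MDM2 fell by 0.32 (SE 0.10, adjusted p = 0.0498) by its brightest probe, but another of its probes passed in the opposite direction. Among the largest rises were LRRD1 (log2 4.26, SE 0.23), FAM229A (3.54, SE 0.40) and PRSS36 (3.37, SE 0.41). In the main processing CD244 and GSPT2 were at least 3.54-fold and 3.43-fold higher. Their log2 changes ran from 0.51 to 3.56 and from 0.59 to 3.9 across settings. MAB21L2, well above background on 1 of 3 unirradiated arrays, rose by 1.90 to 5.17 across settings.

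In total 3707 genes changed, 2713 up and 994 down (73.2% up), with slide and group not separable. With normexp correction 2048 rose and 3587 fell (36.3% up). Among genes with a symbol the main processing gave 1078 up and 767 down, a smaller excess of rises. Genes called as raised had 397 further tested probes, of which 45.8% had the same sign (95% exact binomial interval 40.9% to 50.9%), against 80.8% for genes higher in the knockout-labelled clone after 4 Gy. For genes that fell this share was 72.8% of 250 probes. Without MAKO_4Gy replicate 3 the count was 2452.

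By the test of the difference itself, in which slide and dose cannot be told apart in the knockout-labelled clone, the response differed between the clones in 2000 genes. Of these, 1713 had a higher and 287 a lower change in the knockout-labelled clone, and among those with a symbol 677 and 244. The split over all genes depended on the processing: it was 2527 and 10 on the spike-in scale, 1396 and 417 with normexp and 903 and 19 without a filter. Among the named genes well above background on all 12 arrays, LRRD1 differed by 4.63 (SE 0.32), FAM229A by 3.81 and STAT5A by -1.50. MAB21L2 and VHRT also had a higher response, with 1 of 3 unirradiated knockout-labelled arrays well above background. NRROS, CORO2B, ADAMTS2 and RARRES1 had a lower response, but each had at least 1 group without an array well above background, so no size is given. Of 19 histone genes, 2 had a higher and none a lower response, the same counts when adjusted over the list alone (median 0.42, camera adjusted p = 0.0265), with H1-4 at 0.85 (SE 0.22) and H4C3 at 0.63 (SE 0.17). Of 35 genes of homologous recombination and the Fanconi pathway, 3 had a lower and none a higher response, the same counts when adjusted over the list alone (median -0.12, camera adjusted p = 0.0385): RAD51AP1 at -0.82 (SE 0.21), PALB2 at -0.64 (SE 0.15) and NBN at -0.60 (SE 0.15). With an estimated correlation the adjusted p of each list was 0.853, and fry called neither (adjusted p = 0.298 for histones and 0.1 for recombination). Mitotic, interferon and p53 target genes did not pass for the response as lists (median -0.15, -0.20 and -0.21, camera adjusted p = 0.154, 0.227 and 0.117). The mitotic and p53 lists passed with quantile normalization (0.0298 each), the authors' table (0.0289 each) and without MAKO_4Gy replicate 2 (0.0139 and 0.037). Mitosis also passed without WT_0Gy replicate 2 (0.038), and p53 targets (0.042) and interferon (0.01) without MAKO_0Gy replicate 2. By fry p53 targets passed (0.0106), mitosis (0.624) and interferon (0.64) did not. Other probes of the genes with a higher response had the same sign in 51.8% of 282 cases, and the comparison includes slide 1. Without MAKO_0Gy replicate 2, 3017 genes passed; the histone call was lost without WT_0Gy replicate 1 (adjusted p = 0.083) or WT_4Gy replicate 2 (0.114), and the recombination call under 14 other settings. Those of the genes named were lost under 14 (H1-4 and H4C3), 11 (RAD51AP1), 10 (NBN) and 9 (PALB2 and STAT5A).

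Across all genes tested, the responses of the clones had a Pearson r of -0.008 and a Spearman rho of 0. Genes are not independent replicates. Without the filter on dim probes r was 0.376. Slide and dose cannot be told apart in the knockout-labelled clone. Neither these correlations nor the overlap of calls below therefore shows whether the clones respond alike to irradiation. The 2 genes past the threshold in the wild type-labelled clone moved in the same direction and passed in the knockout-labelled clone as well, 1 rise and 1 fall, where independent lists would share 0.11 and 0.04.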

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

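The tests of other probes and of the background of a single array were chosen after the results they bear on had been seen; the splits of the arrays were not. The test of the difference of responses called 2000 genes and 2 gene lists. Its knockout-labelled part equals slide 1 against slide 2, so a differing response to dose cannot be told apart from slide. The median difference of response was 0.42 for histone genes and -0.12 for homologous recombination and the Fanconi pathway. Among named genes it was 4.63 for LRRD1, 3.81 for FAM229A, 3.73 for LNCRNA-IUR and -1.50 for STAT5A. MAB21L2 and VHRT, well above background on 1 of 3 unirradiated knockout-labelled arrays, had fitted values of 4.73 and 3.68. Across settings these ran from 2.43 to 5.81 and from 1.66 to 4.31. The call of STAT5A was lost under 9 of 22 other settings, that of MAB21L2 under 3 and that of LNCRNA-IUR under 1. The fitted values of -4.13 for NRROS, -2.29 for CORO2B, -2.21 for ADAMTS2 and -1.85 for RARRES1 are no measured sizes, since each of these genes had at least 1 group with no array well above background; for NRROS these were the irradiated knockout-labelled and the unirradiated wild type-labelled arrays.

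A related pattern, the 2713 genes (1078 with a symbol) called as raised by 4 Gy in the knockout-labelled clone relative to the 75th percentile, may be a matter of single probes. A change of the transcripts would move other probes of the same genes; those 397 probes, which cover 309 of the 2713 raised genes, had a median log2 change on that scale of -0.03 (95% bootstrap interval -0.07 to 0) where the called probes had 0.75, which argues against it for the genes with a further probe. The high background of unirradiated knockout-labelled replicate 2 is argued against too, since 3805 genes rose without that array. A slide effect on single probes predicts a share near chance, and 45.8% of the other probes had the same sign. It stays open whether slide, labelling or another step of the unirradiated knockout-labelled arrays is behind it, as only these arrays of the series are on slide 1. A response of the genes measured by 1 probe also stays open.

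For the difference of responses, 1 of 100 drawn splits by dose within the clones gave as many genes, the real one with 2000, and the highest other gave 1963. The 10 other draws that kept the real dose groups of the knockout-labelled clone gave 1210 to 1963 genes and the remaining 89 at most 1, so among these draws high counts came with the contrast of slide 1 with slide 2. These draws cannot exclude chance: the 89 mix arrays of slides 1 and 2 within a group, and the 10 that did not came close to the real count. They also say nothing about dose: the knockout-labelled part of the contrast equals slide 1 against slide 2, and scrambled doses in the wild type-labelled clone gave up to 1963 genes. For the other comparisons, 6 arrays make 10 splits, too few for a share under 0.05. The real split gave 2 genes for 4 Gy in the wild type-labelled clone, 3707 in the knockout-labelled clone, 9797 between the clones without irradiation and 6521 after 4 Gy, each as 1 of 10, and the highest other split gave 0 in limma in all 4.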

How the results depend on the processing

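The fits on slide 2, with slide 3 as a block and on the spike-in scale, and the alternatives for the correlation of the responses other than that over genes past the threshold, were added after the data were seen. Genes changed by 4 Gy in the wild type-labelled clone numbered 2; there were 0 with median scaling, without a filter, with the replicate block, with only the groups compared, on slide 2 and with slide 3 as a block, 1 with normexp, the strict filter, a variance trend or spike-in scaling, and 0 (range 0 to 0) without any single array. Genes changed in the knockout-labelled clone numbered 3707, against 5635 with normexp, 1991 without a filter (more genes tested) and 1949 with only the groups compared (fewer arrays), and 2452 (without MAKO_4Gy replicate 3) to 4887 (without MAKO_0Gy replicate 2). Without a filter 3695 genes differed between the clones after 4 Gy and 922 in response. Besides the adjusted p, a 2-fold threshold left 1290, 3598, 1826 and 1115 genes for 4 Gy in the knockout-labelled clone, the clones without irradiation, the clones after 4 Gy and the responses. Leaving out 1 array gave 7846 to 10785 genes between the clones without irradiation, 4858 to 5639 after 4 Gy and 1343 to 3017 (without MAKO_0Gy replicate 2) in response. Scaling to 7 spike-ins, run for SLC3A2 and the gene counts, gave 13458 genes for 4 Gy in the knockout-labelled clone and 19985 and 16090 between the clones without irradiation and after 4 Gy, because it moves all genes of an array alike. SLC3A2 went with this common shift (median of all genes -1.07 and -0.71), at -1.25 without irradiation (adjusted p = 5.1e-05) and -0.77 after 4 Gy (0.0026), and passed under no other setting; without 1 array its difference ran from -0.32 to -0.13 without irradiation and from -0.23 to 0.03 after 4 Gy.

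Of 23 list calls, none held with an estimated correlation. Lists with an estimate below the preset lost theirs too, as p53 targets (-0.015) and amino acid transporters (-0.009) between the clones at 0 Gy. What ended these calls was not tested. Fry made 37 calls, 17 of these 23 and 20 others; it lost all 3 in the wild type-labelled clone (adjusted p = 0.456 for mitosis, 0.464 for histones and 0.842 for interferon), both of the response (histones 0.298, recombination 0.1) and histones between the clones after 4 Gy (0.0869); the preset correlation is 0.01 and the estimated ones ran from -0.015 to 0.822. The correlation of the responses was 0.376 without a filter and -0.061 to 0.052 without single arrays. Under normexp, MDM2 reversed to 0.84 (4 Gy, knockout-labelled), -0.35 (clones, 0 Gy) and 0.84 (response), and SLC22A10 to -0.22 (4 Gy, knockout-labelled) and 0.11 (clones, 0 Gy); with the mean of probes MDM2 reversed to 0.17 for 4 Gy in the knockout-labelled clone. The cause of these changes was not tested. Quantile scaling and the authors' table moved the median of all genes for 4 Gy in the knockout-labelled clone from -0.06 to 0.05 and for the response from -0.06 to 0.06, and normexp that of the clones at 0 Gy from -0.07 to 0.08. The numbers do not clearly pair the arrays: 7 of 18 same-numbered pairs had correlated deviations over 0.1 (-0.17 to 0.32), and an array correlated best with its own number in 16 of 36 cases. On slide 2, same-numbered pairs of replicates 1 and 2 correlated at 0.14 to 0.32, so a weak pairing there stays open. With the replicate block the counts were 0, 3728, 10232, 7132 and 1932 genes, in the order of dose in the wild type-labelled and knockout-labelled clone, clones at 0 Gy and 4 Gy, and response. Among named genes, 3450 recomputed values kept direction and side of the threshold, 268 no longer passed, 13 newly passed and 6 reversed, with sign changes of values that did not pass counted as kept; among the lists called, 404 kept both and 65 no longer passed. Lists not called here were newly called 82 times by camera at its preset correlation, in 35 pairs of list and comparison. Among these were 12 without a filter and 9 each with quantile scaling, normexp and the authors' table. Without MAKO_0Gy replicate 2 or MAKO_4Gy replicate 2 there were 10 each. The 20 other calls of fry are not in this count, while the 65 lost calls include fry and the estimated correlation. The recombination list lost its call in 14 settings (adjusted p = 0.0598 with median scaling, 0.903 with normexp), a strict filter ended the calls of p53 targets (0.0649) and mitosis (0.058) at 0 Gy and the mean of probes that of mitosis (0.0601), and mitosis at 0 Gy also lost it without WT_0Gy replicate 2 (0.133). Signal over background limits genes given as at least N-fold.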

Other observations

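The tests of slide 2, of the genes next to SLC3A2, of a wrong label and of the spike-ins were chosen after the results were seen. Without irradiation, several groups had members that differed between the clones in both directions and did not pass as lists by camera. Of 27 NRF2 targets, 11 were higher and 8 lower in the knockout-labelled clone, the same counts when adjusted over the list alone (camera adjusted p = 0.381, 0.0652 by fry). Of 19 hypoxia genes, 8 were higher and 6 lower, again the same when adjusted over the list alone (camera adjusted p = 0.226, 0.00143 by fry). Of 20 glycolysis genes, 3 were higher and 8 lower (4 and 9 when adjusted over the list alone, camera adjusted p = 0.185, but 0.0256 without a filter, 0.0265 with normexp and 0.00398 by fry), and of 18 integrins 5 were higher and 2 lower (5 and 3 when adjusted over the list alone, camera adjusted p = 0.185, 0.0291 by fry).

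Some genes were on in 1 clone only: 95 were well above background on 6 of 6 knockout-labelled arrays and on none of the wild type-labelled ones, and 44 the other way round. Over 13641 genes placed by neighbour order, the clone differences without irradiation and after 4 Gy correlated at 0.81 across single genes. Over all 24291 genes tested, placed or not, the same differences had a Pearson r of 0.739 and a Spearman rho of 0.571. Single genes are not independent replicates. Across medians of 30 neighbours of the placed genes, in windows that overlap, the correlation was 0.86. The lowest window on chromosome 2 had a median of -0.85 after 4 Gy and -0.69 without irradiation, and the highest on chromosome 10 had 0.96 and 1, and on chromosome 8 0.86 and 1.04. Others had opposite signs at the 2 doses, as the highest on chromosome 6 (0.39 and -0.02) and the lowest on chromosomes 17 (-0.25 and 0.01) and 20 (-0.19 and 0.03). In 1000 shuffles of the genes the lowest window lay between -0.59 and -0.32.

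The wide difference between the clones is the second pattern. A slide effect as the whole cause after 4 Gy is argued against, since 5517 genes differed on slide 2 alone. Copy number differences of chromosome segments may add to it, but as its main source they are argued against for the genes placed by neighbour order: subtracting the median of their 30 neighbours took 19.5% (95% exact binomial interval 17% to 22.3%) of 906 genes with at least a 2-fold difference below 2-fold. Of 3704 placed genes that differed by less than 2-fold, 18.3% (17% to 19.6%) lost at least as much of their difference as they kept. With the windows shuffled 100 times this share was 8.2% to 10.6%, and segments shorter than such a window stay open. Window medians after 4 Gy lay between -0.85 and 0.96, so subtracting them could not take genes with much larger differences below 2-fold. No shuffle was run for the first share, and both intervals treat genes as independent although their windows overlap. Whether fewer SLC3A2 copies or any other difference between clones is behind it cannot be told apart, with 1 clone per genotype.

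The third pattern is the near-equal SLC3A2 level relative to the 75th percentile; the spike-in scale (-1.25 and -0.77) does not bear on it, as it moved the median of all genes to -1.07 and -0.71. Of 668 genes within 0.5 of the level of SLC3A2, 3% (95% exact binomial interval 1.8% to 4.6%) differed at least 2-fold after 4 Gy, against 7.5% of all genes. A compressed scale of bright probes would give such a share. Genes of this brightness may also differ less by themselves, so the share does not decide it. No SLC3A2 spot was saturated. The 30 genes next to SLC3A2 had a median of -0.53 after 4 Gy and -0.41 without irradiation, with 31 windows in all as low or lower after 4 Gy, and 3 of 1000 shuffles had a window as low anywhere. A lower copy number of the surrounding segment would lower SLC3A2 too, so this test does not bear on the near-equal level; SLC3A2 itself, at -0.13, lay above 25 of these 30 neighbours. A mislabelled clone cannot be told apart from full compensation by the remaining copy, since both allow that -0.13 on this scale. Whether the edited alleles still give RNA that the probe detects is not known here, so the near-equal level alone does not speak against the label.

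The spike-in E1A_r60_n11, as log2 over the 75th percentile of the array, was 4.71 ± 0.08 (SD, n = 3) in unirradiated and 4.41 ± 0.17 in irradiated wild type-labelled arrays, and 5.92 ± 0.08 and 5.11 ± 0.25 in the knockout-labelled ones. The mean of the 7 spike-ins with all spots well above background and unsaturated was higher in the knockout-labelled arrays by 1.00 without irradiation (0.27 to 1.45 for single spike-ins) and by 0.64 after 4 Gy (0.56 to 0.70). Without irradiation this difference cannot be told apart from slide. Whether the amount of RNA, of spike-in or the labelling differed was not tested.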
